A study of Mus musculus with 40 samples.

How the data were processed

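Genomic DNA of mouse T-cell lymphomas was profiled on 40 Agilent 2-colour comparative genomic hybridisation arrays. Per the labels, the tumours came from mice that lack Atm and carry a telomerase reverse transcriptase fused to an oestrogen receptor domain (TERT-ER), in which 4-hydroxytamoxifen (4-OHT) switches telomerase on. Per the labels, the tumour DNA carried Cy3, the green dye. What the red channel held is not given in the sources used here. Samples were grouped by their labels: 10 tumours of generation 1 (G1) on 4-OHT, 14 of generation 3 (G3) on 4-OHT, 5 of G3 on vehicle, 3 samples labelled ALT (852, 2072P and 2186P), and line 778 with 1 parental sample, 3 telomerase-positive samples (778_Tel) and 4 ALT samples (778_ALT). ALT stands for alternative lengthening of telomeres, a way to keep telomeres without telomerase. The labels name a SCID recipient strain for all 40 samples, a passage, the 4th, for 9 of them (2072P, 2186P, 778_Tel and 778_ALT) and parental in its place for 1. Per the labels, 778_ALT was on vehicle and 778_Tel, 2072P and 2186P on 4-OHT. The 29 G1 and G3 tumours labelled as telomerase-positive, outside line 778's passaged samples, carry no passage and are called primary tumours here. Nothing in the labels says that the 778 samples of 1 group came from separate animals, so their p-values measure the spread between these samples, which may be technical.

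Per the file headers, the authors scanned and quantified the arrays with Agilent Feature Extraction version 10.5.1.1, and each file gives a processed signal per spot and channel, an intensity on a linear scale after background subtraction, spatial detrending and linear dye normalisation within the array. Per the file headers, each file also gives the log10 ratio of the red over the green processed signal, and the median intensity of each spot and its background. The authors also deposited a value table per array design, on a log2 scale by comparison with the spot values. Against those, the deposited log2 ratios ran in the direction of green over red on all 40 arrays, with r from 0.599 to 0.978 across probes, which are not independent replicates. The median of the deposited values ranged from -0.20 to 0.01 between arrays, and the centring and any smoothing behind them stay unknown. Steps between neighbouring probes had an autocorrelation of -0.49 in the spot values of tumour 2379 and of -0.29 in its deposited values. The deposited values differed in this between arrays, from -0.497 to -0.487 in scan 1 and from -0.492 to -0.472 in scan 4, but from -0.287 to -0.281 in scan 3, from -0.290 to -0.259 in scan 5 and from -0.291 to -0.269 in scan 6, and -0.171 for 852. They therefore differed within 778_ALT and within 778_Tel, which lie in scans 3 and 4.

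The ratio used here was log2 of the green over the red processed signal, without control spots and without spots with outlier marks, averaged over spots of 1 probe and centred on the autosomal median of each array. The 3 array designs are called older (10 arrays), newer and second newer (1 array, 778_ALT 1, without X probes). The header of the older design names the build mm7 and the newer designs name mm9. Probe positions were taken from the newer design (mm9) through shared probe names, and no coordinate was converted. Of 235402 probes on the older design, 214962 were on the newer one, and 202636 autosomal probes common to all 3 designs were used. The arrays fell into 6 scans. Saturated spots reached at most 0.252% of an array. Signal limited the precision on 2 arrays in particular. On the array of G3_OHT 475, 45.6% of spots were well above background in green and 20.4% in red, and 778_ALT 4 had 69.1% in green. The array of 778_Tel 2 had 40462 outlier spots. Green signal was also weak against red on part of scan 6. Its median after background subtraction ranged there from 80.9 (G1_OHT 2275) to 1015 (G3_OHT 2713), with red from 555 to 873. In scan 5 green ranged from 650 to 1046 and red from 567 to 1128. The number of arrays limits the precision of every group value.

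Each chromosome was divided into pieces of constant level by exact least-squares (Potts) segmentation with a penalty of 4 times the noise variance times the natural log of the probe number, and at least 5 probes per piece. A breakpoint was a step of at least 0.3 between neighbouring pieces, and a piece at or beyond 0.3 in size counted as gained or lost. Focal pieces were shorter than 5 Mb. Ends within 20 kb counted as equal. Groups were compared by an exact two-sided permutation test of the difference of means, with labels permuted within array design for the primary tumours. The files used here pair no probe with a gene name. The comparisons planned per gene were therefore made on 1-Mb windows of mm9, with limma 3.58.1 in R 4.3.3 and Benjamini-Hochberg adjustment at 0.05, over 2409 autosomal windows (2566 with X in line 778, where 778_ALT 1 has no X value). The fits of the primary tumours held all 3 groups and the array design as a term. Frequencies of gain and loss were compared by Fisher's exact test over 416 distinct patterns of tumours. Chromosome levels are medians of the windows of a chromosome, and their tests over 19 autosomes were chosen after seeing the data. The other scripts ran on Python 3.11.15 with NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1, Numba 0.67.0 and Matplotlib 3.10.9.

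The rule for named genes, fixed before the data were examined, named 15 genes (among them Myc, Notch1, Ikzf1, Bcl11b, Trp53, Cdkn2a, Atm, Tert, Terc, Atrx, Daxx, Ppargc1a, Ppargc1b and Sod2), the members of 5 gene lists that pass a test or are often gained, lost or hit by a focal piece, and in each comparison up to 5 items with the largest rise and fall past the threshold with at least 3 probes and at most 1 per 5 Mb. The last part was applied to windows. Without gene positions on mm9, the others could be applied only to chromosomes, taken from a RefSeq table of GRCm38.p6 without its coordinates. The lists were T-cell lymphoma drivers, telomerase and shelterin, ALT-linked recombination and chromatin, mitochondrial biogenesis and oxidative defence, and the DNA damage response.

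Both methods were tested on simulated data. The simulated pieces had at least 20 probes, so shorter pieces were not covered. The simulated windows were drawn independently, with only the groups compared and no array design term. Real windows of a chromosome move together, so the shares below do not give the power of the real fits. Of 38 steps made, the segmentation found 38 at the lowest probe noise of the arrays (0.0958), 34 at the median noise (0.178) and 9 at the highest (0.396). Among 2409 windows, limma recovered 73% of 100 windows changed by 0.3 and 96% of 100 changed by 0.6 for G3 against G1 on 4-OHT, with 7 unchanged windows called. Those shares were 59% and 90% for vehicle against 4-OHT in G3, 68% and 92% for G3 on vehicle against G1, and 66% and 81% for 778_ALT against 778_Tel. Alternatives covered the deposited values, other penalties, thresholds and piece lengths, the array design, the scan, the slide, centring, windows of X and left-out samples. An alternative fixed in advance called for normexp background correction of mean signals. Of the 40 files, 0 have a mean signal column and 40 a median signal column, so normexp (offset 50) was run on median spot and background signals, chosen once the columns were known, and normexp on mean signals was not run. The alternative without antigen receptor loci was not run because their mm9 positions were not used here.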

Results

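Copy number was measured in T-cell lymphomas of Atm-deficient TERT-ER mice. Tumours of generations 1 and 3, tumours on vehicle and on 4-OHT, and telomerase-positive and ALT samples of the same tumour line were compared. The 40 arrays held 29 primary tumours (10 G1_OHT, 14 G3_OHT and 5 G3_VEH, named by generation and treatment with 4-OHT or vehicle) and 11 further samples, 8 of them of line 778. Probe noise ranged from 0.0958 to 0.396 log2 units between arrays. All regions are given on mm9.

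Short losses on chromosomes 6, 14 and 13 were the most frequent focal changes of the primary tumours. A loss at chromosome 6, 41252584 to 41264016, was called in 28 of 29 tumours, a loss at chromosome 14, 54727834 to 54735315, in 27, and a loss at chromosome 13, 19281464 to 19297942, in 23. Their median levels over the primary tumours were -0.88, -3.70 and -3.04. These are the chromosomes that carry the T-cell receptor beta, alpha with delta, and gamma genes in the GRCm38.p6 table. The mm9 positions of those genes were not used here. The levels were low in the green over red ratio, and 39, 38 and 39 of the 40 arrays lay at or under -0.3 in them. Other frequent losses lay at chromosome 12, 116794535 to 116867808 (13 tumours), and chromosome 16, 6617085 to 6632273 (12 tumours). In scans 1, 5 and 6 they were called in 2, 2 and 9 tumours (chromosome 12) and 3, 3 and 6 tumours (chromosome 16). Levels in the chromosome 12 region ranged from -2.09 to 1.16 between arrays. The loss on chromosome 16 was also called in all 8 samples of line 778 outside the primary tumours, as were the losses on chromosomes 6 and 14.

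Gain of chromosome 15, which carries the oncogene Myc, the interleukin 7 receptor gene Il7r, the heterochromatin gene Cbx5, the mitochondrial thioredoxin gene Txn2 and the DNA repair gene Xrcc6, was the most frequent change of a whole chromosome. Its level was at or above 0.3 in 16 of 29 primary tumours, 6 of 10 G1_OHT, 8 of 14 G3_OHT and 2 of 5 G3_VEH, and lost in 0. Chromosomes 12 (Bcl11b, a T-cell transcription factor) and 16 (Runx1) were at or above 0.3 in 5 tumours each, and chromosome 17 (Daxx and Sod2) in 4. The chromosomes of Notch1 (2), Ikzf1 and Trp53 (11), Terc (3), Tert (13) and Ppargc1a (5) were gained or lost in 0 of 29, that of Ppargc1b (18) in 0, that of Cdkn2a (4) was gained in 1 and that of Atm (9) was gained in 1. Atrx lies on X, which was left out of the main comparisons between tumours of different animals. It entered only an alternative of the window fits, autosomes with X. A chromosome level says nothing of a short change at the gene itself.

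**Figure D1:**
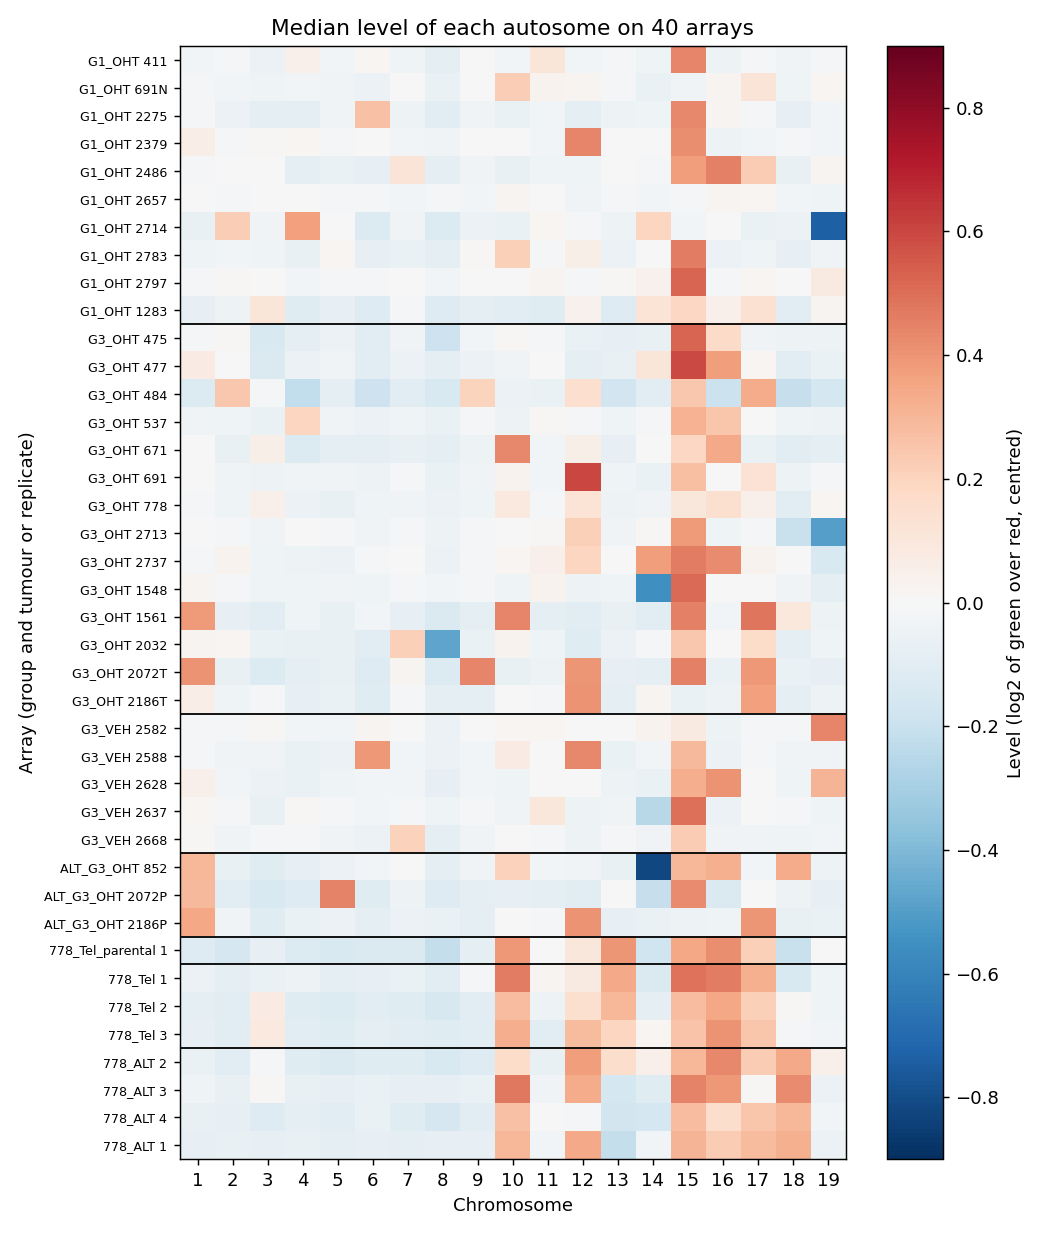
Level of each autosome (columns, log2 of green over red, colour) on each of 40 arrays (lines of the map, by group). Chromosome 15 is at or above 0.3 in 16 of 29 primary tumours, and chromosome 18 is high in all 4 778_ALT samples.

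Generation was compared among tumours on 4-OHT. A larger part of the autosomes was altered in G3_OHT tumours, 17.1% ± 8.45 (SD, n = 14), than in G1_OHT tumours, 11.3% ± 5.18 (SD, n = 10). The difference adjusted for array design was 6.71 percentage points (exact two-sided permutation test, p = 0.0390). Gains covered 13.1% ± 5.72 and 9.38% ± 5.08, and losses 4.07% ± 5.37 and 1.94% ± 1.31. Without G3_OHT 484, with losses of 21.9% (1.29% in the deposited values), the G3_OHT mean of losses was 2.70% ± 1.59 (SD, n = 13). With the scan as a block the difference was 5.43 (exact permutation p = 0.161), and within scans 1, 5 and 6 it was 10, 4.66 and 1.26, with 2, 1 and 7 G1_OHT arrays. Without the tumours 691 and 691N, which share focal losses although labelled with different generations, the difference was 5.80 (exact permutation p = 0.0732). Breakpoints numbered 120 ± 105 in G3_OHT and 187 ± 120 in G1_OHT, an adjusted difference of -34.1 (exact permutation p = 0.456) that turned to 52.7 with the scan as a block (p = 0.162) and was 59.0, 21.2 and 63.4 within scans 1, 5 and 6. In the windows, limma called 0 of 2409 as different, with 130 at an unadjusted p under 0.05 and a smallest adjusted p of 0.761. Within scan 5, with 1 G1_OHT array, it called 57, and within scan 6, with 2 G3_OHT arrays, 3. By frequency, Fisher's exact test with adjustment called 0 patterns, with 14 windows at an unadjusted p under 0.05. The lowest p, 0.00884 (adjusted p 1), was for gain of chromosome 15 from 102000001 to 104000000, in 13 of 14 G3_OHT and 4 of 10 G1_OHT tumours. On chromosome 16 from 87000001 to 97000000, 12 of 14 and 4 of 10 were gained (Fisher's exact p = 0.0324, adjusted p 1).

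**Figure D2:**
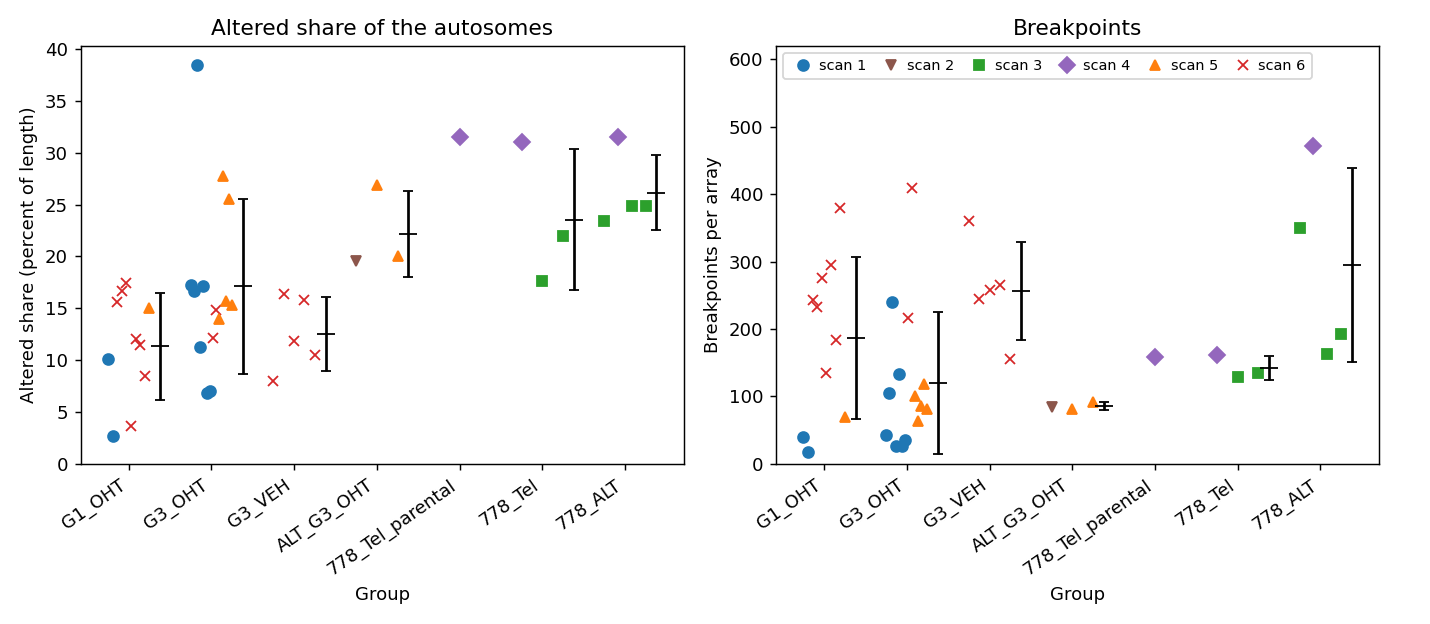
Altered share of the autosomes (left, percent of length) and breakpoints (right) of each array by group, with the mean and SD beside each group of over 1 array; symbols and colours give the scan. The primary tumours of scan 6 had 261 breakpoints on average, against 73.9 in scan 1 and 86.7 in scan 5.

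Treatment was compared in G3 tumours, vehicle against 4-OHT. Both groups are labelled as telomerase-positive, so the labels do not make this a comparison of tumours without and with telomerase. All 5 G3_VEH arrays are of the newer array design. The permutation tests adjusted for design therefore set them against the 7 G3_OHT arrays of that design only. Group means and counts of tumours cover all 14 G3_OHT tumours. The altered share was 12.5% ± 3.58 (SD, n = 5) in G3_VEH, a difference of -5.39 percentage points from G3_OHT (exact permutation p = 0.126), and -0.965 with the scan as a block, which is also the value within scan 6 (exact permutation p = 0.762). Chromosome 19 was higher in G3_VEH, 0.13 ± 0.23, than in G3_OHT, -0.09 ± 0.13, with an adjusted difference of 0.26 (exact permutation p = 0.00253, adjusted over 19 chromosomes 0.0480). It was at or above 0.3 in 2 of 5 G3_VEH tumours, 2582 and 2628, and in 0 of 14 G3_OHT tumours. With the scan as a block the difference was 0.45 (exact permutation p = 0.0952), or 0.27 (p = 0.333) without 2713, 1 of the 2 G3_OHT arrays of scan 6 and the lowest of G3_OHT at -0.50. Without 2713 and without that block it was 0.20, and with arrays centred on the mode it was 0.24 (p = 0.0644). The call over 19 chromosomes was lost in 12 of 14 alternatives by Bonferroni adjustment, and held only with the deposited values and with at least 3 probes per window. Leaving out 1 tumour at a time (each G3_VEH tumour and 2713), the difference was 0.18 to 0.30, with adjusted p from 0.0576 to 0.921. G3_VEH tumours had 257 ± 72.5 breakpoints, 103 more than G3_OHT after adjustment (exact permutation p = 0.130). All 5 G3_VEH arrays lay in scan 6, with 2 G3_OHT arrays, and there the difference was -55.9 (exact permutation p = 0.524). In the windows limma called 0 of 2409, with 180 at an unadjusted p under 0.05 and a smallest adjusted p of 0.549, and 3 within scan 6.

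G3 tumours on vehicle were also compared with G1 tumours on 4-OHT. Here the permutation tests adjusted for design rest on the 5 G3_VEH and the 8 G1_OHT arrays of the newer design. The altered share differed by -0.0530 percentage points (exact permutation p = 0.983), and by 0.296 with the scan as a block or within scan 6 (exact permutation p = 0.929). Breakpoints differed by 30.0 (exact permutation p = 0.573) and by 7.46 with the scan as a block or within scan 6 (exact permutation p = 0.889). Chromosome 15 was at 0.28 ± 0.15 (n = 5) and 0.28 ± 0.22 (n = 10). In the windows limma called 0 of 2409, with 78 at an unadjusted p under 0.05 and a smallest adjusted p of 1.

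In line 778, chromosome 18 was higher in the ALT samples, labelled as on vehicle, than in the telomerase-positive samples, labelled as on 4-OHT. This chromosome carries Ppargc1b, a coactivator of mitochondrial genes, Atp5a1, a subunit of the mitochondrial ATP synthase, and Zeb1, a transcription factor. Of the other lists, telomerase with shelterin, ALT-linked recombination and the DNA damage response, 0 genes lie on chromosome 18. Its level was 0.35 ± 0.05 (SD, n = 4) in 778_ALT and -0.05 ± 0.08 (SD, n = 3) in 778_Tel, and the difference of 0.39 had an exact permutation p of 0.0286, the smallest that 35 assignments allow, or 0.543 adjusted over 19 chromosomes. The difference was 0.39 with the scan as a block (exact permutation p = 0.05, the smallest it allows), 0.32 within scan 3 (3 and 2 arrays) and 0.56 within scan 4 (1 array each). Of 2566 windows, limma called 47, all higher in 778_ALT and all on chromosome 18, with 183 windows at an unadjusted p under 0.05. From 3000001 to 38000000 the level was 0.36 ± 0.07 against -0.06 ± 0.04, and from 55000001 to 78000000 it was 0.49 ± 0.12 against 0.02 ± 0.08. The part between, from 38000001 to 55000000, was low in both, at -0.62 ± 0.28 and -0.76 ± 0.23. The parental sample (1 array) was at -0.21 and -0.13 in the outer parts and at -1.10 between them. The windows with the largest rise, at most 1 per 5 Mb, started at 59000001 (0.54, limma adjusted p 0.0286), 77000001 (0.52), 27000001 (0.50), 6000001 (0.47) and 68000001 (0.47).

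The count of 47 windows changed when single arrays were left out and when the scan was taken into account, while the chromosome 18 difference stayed between 0.35 and 0.42 leaving out each sample. The count was 31 with the scan as a block and 0 within scan 3 (5 arrays), 123 without 778_ALT 2 (65 windows higher in 778_ALT and 58 lower), 27 without 778_ALT 3, 18 without 778_ALT 1, and 0 without any 1 of 778_ALT 4, 778_Tel 1, 778_Tel 2 and 778_Tel 3. It was 0 with arrays centred on the mode (231 at an unadjusted p under 0.05). Chromosome 13, which carries Tert, was at -0.09 ± 0.17 in 778_ALT and 0.28 ± 0.08 in 778_Tel, a difference of -0.37 (exact permutation p = 0.0571), with 778_ALT 2 at 0.16. The altered share was 26.2% ± 3.61 in 778_ALT and 23.6% ± 6.83 in 778_Tel, a difference of 2.60 (exact permutation p = 0.514), or 3.35 with the scan as a block (exact permutation p = 0.05), 4.57 within scan 3 and 0.426 within scan 4. Breakpoints were 295 ± 144 and 142 ± 17.8, a difference of 153 (exact permutation p = 0.171), or 164.5 with the scan as a block (exact permutation p = 0.150), 103.8 within scan 3 and 310.0 within scan 4. Chromosomes 10, 15, 16 and 17 were high in both, at 0.30 and 0.36, 0.33 and 0.34, 0.30 and 0.40, and 0.19 and 0.26 in 778_ALT and 778_Tel.

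**Figure D3:**
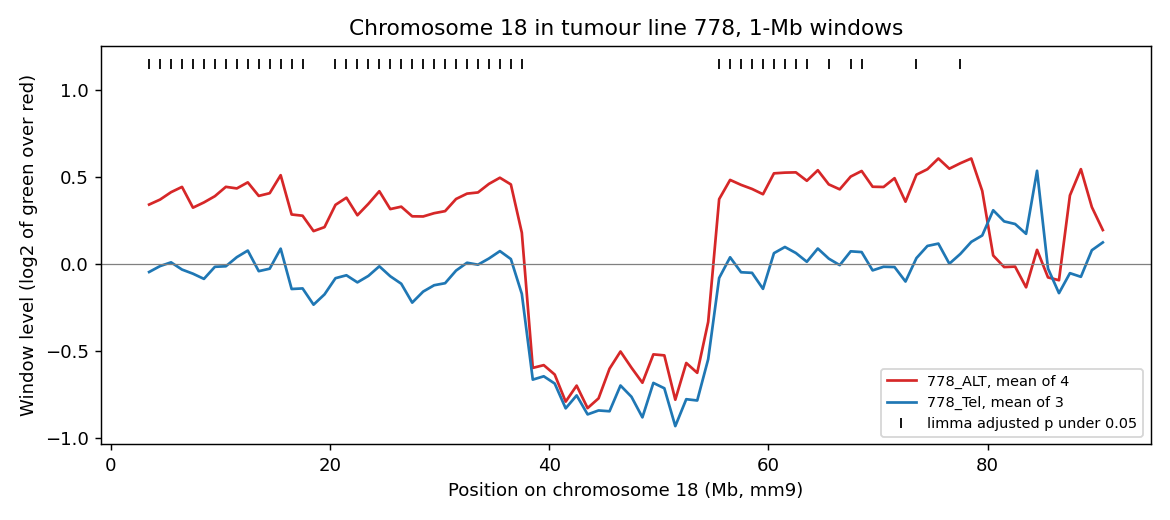
Level of 1-Mb windows along chromosome 18 (mm9, Mb) in line 778, as group means (log2 of green over red); ticks mark windows with a limma adjusted p under 0.05. Both groups are low between 38000001 and 55000000, and 778_ALT is higher from 3000001 to 38000000 and from 55000001 to 78000000.

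ALT and telomerase-positive samples were also compared over lines 2072, 2186 and 778. In line 2186 the ALT sample had chromosome 1 at 0.35 against 0.06 and kept the gains of chromosomes 12 (0.40 and 0.40) and 17 (0.40 and 0.37). In line 2072 the ALT sample had chromosome 5 at 0.45 against -0.06, while chromosomes 9, 12 and 17 were at -0.09, -0.10 and 0.01 against 0.44, 0.39 and 0.39 in the telomerase-positive sample. Chromosome 18 differed by 0.01 in line 2072 and 0.02 in line 2186. With the line as a block limma called 0 of 2409 windows, with 17 at an unadjusted p under 0.05 and a smallest adjusted p of 0.882. Lines 2072 and 2186 have 1 array per state, and there the ALT samples are of passage 4 and their partners carry no passage, so state cannot be separated from passage in these lines.

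**Figure D4:**
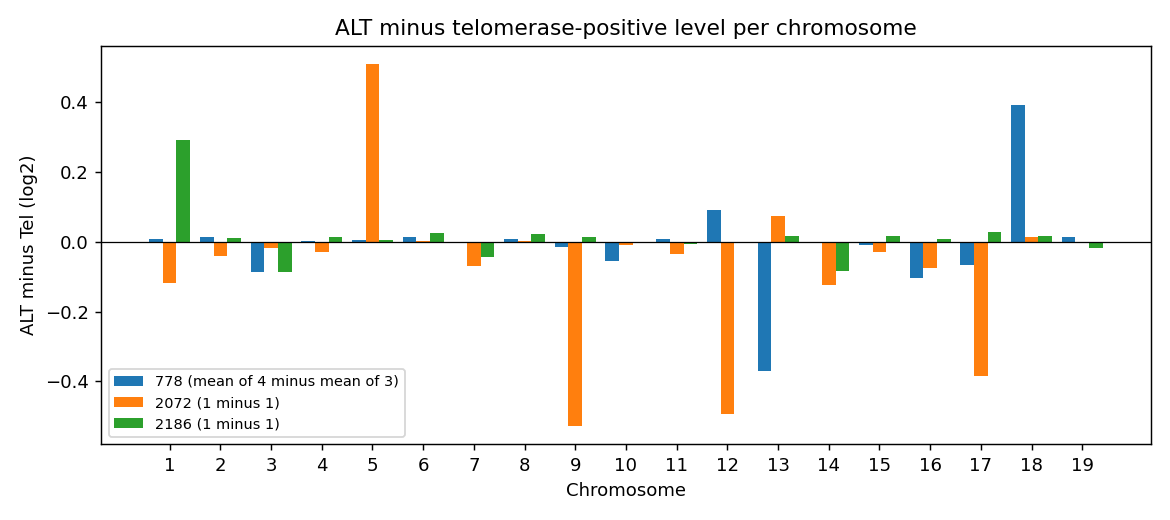
ALT minus telomerase-positive level of each autosome (log2) in the lines 778, 2072 and 2186. Chromosome 18 differs by 0.39 in line 778, chromosome 5 by 0.51 in line 2072 and chromosome 1 by 0.29 in line 2186.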

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

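The comparisons of chromosome levels, the tests of chromosome 18 by scan, by swapped labels and in the other lines, the test of line 2072 within its scan, the test of scan 6 at equal noise and the test of shared short pieces were chosen after the result was seen. Of 18 checks of single samples against their group, 3 found a sample far from the others, and chance does so in about 1 of 20 groups. The level of chromosome 19 of G1_OHT 2714 was -0.73, against -0.04 in the next G1_OHT tumour, while that of G3_OHT 2713, on the same slide, was -0.50. Chromosome 13 of G1_OHT 1283 was at -0.11, against -0.05. Chromosome 13 of 778_ALT 2 was at 0.16, against -0.16 in the nearest 778_ALT sample. In samples outside the group comparisons, chromosome 14 of the ALT sample 852 was at -0.82 and its chromosome 18 at 0.33, where the 29 primary tumours reach -0.55 and 0.10. Chromosome 13 of the parental 778 sample was at 0.40, where the primary tumours reach 0.01.

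Chromosome 18 was higher in 778_ALT than in 778_Tel. The chromosome 18 difference was 0.32 or more within both scans that hold both groups, which argues against the scan. It was 0.47 after subtracting the mean of the 5 chromosomes that correlate most with chromosome 18 over the primary tumours. With chromosome 13, itself lower in 778_ALT, left out of them, it was 0.40. The other 4 differed by -0.056 to 0.014 in line 778, so they did not share the difference. Their r with chromosome 18 was 0.283 to 0.433, too low to show that they would follow a trend along the genome. This test therefore does not decide about such a trend. It was at least 0.32 leaving out any 1 sample of each group. The levels of the groups did not overlap, so leaving out samples could not remove the difference and decides nothing about a swap. The difference was 0.39 without 778_ALT 2, so it did not rest on that sample. In profiles without chromosome 18, 778_ALT 2 was closer to 778_Tel (mean r 0.889) than to 778_ALT (0.767). Its own chromosome 18 level, 0.34, lay with 778_ALT (0.30 to 0.42) and above 778_Tel (at most 0.01). Each 778_Tel sample was closer to its own group (mean r 0.869 to 0.921) than to 778_ALT (0.803 to 0.815). In these profiles a swap was to leave 1 sample of each group closer to the other group, and no 778_Tel sample was. Telomerase state may contribute, but the smaller of the differences in lines 2072 and 2186 was 0.013 with 1 array per state and only the ALT samples passaged, which leaves this open. Treatment differs with state in line 778, and neither it nor a founder clone of the ALT samples was tested. Of the 35 splits of the 7 samples, 2 gave at least the real 47 windows, the real one included, and the other gave 97, so chance is not excluded. That split sets 778_Tel 1, 2 and 3 with 778_ALT 2 against the other ALT samples, a structure of the samples.

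The ALT sample of line 2072 had another chromosome profile than the telomerase-positive sample (r = 0.383 across windows). The samples of line 2186 had an r of 0.891, and 26 pairs of different tumours in scan 5 had 0.175 to 0.502 (median 0.338). By r, the samples of line 2072 were no more alike than different tumours. If array noise were the cause, r was to rise to 0.8 in the deposited values or in piece levels; the higher was 0.369. The samples share 13 focal losses with equal ends, and the test set in advance came out on the side of another tumour, since unrelated primary tumours share up to 36. That pair, 2713 and 2714, lies on 1 slide of scan 6, where the median of 91 pairs is 6 and the next highest pair shares 23. The cause of the 36 stays open, so this test was read as undecided. Within scan 5, the share of 59.1% lay above the highest of 26 pairs of different tumours (27.3%). The samples lie on 1 slide, where the highest of 9 other pairs, of different tumours, was 32.7%. These shares argue against a wrong label that brings in an unrelated tumour. They cannot tell 1 tumour from another tumour of the same animal. A subclone selected during passage stays open as an untested hypothesis.

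Primary tumours of scan 6 had more breakpoints, 261 against 73.9 and 86.7 in scans 1 and 5. With pieces of at least 20 probes they had 45 to 97, against 13 to 190 in scan 1 and 39 to 71 in scan 5. The excess therefore rested mostly on shorter pieces. Within scan 6, breakpoints and probe noise had a Spearman rho of 0.165 (permutation p = 0.574) and a Pearson r of 0.318 (permutation p = 0.269) over 14 tumours. The value 2 standard errors above rho, 0.649, lies above the 0.5 set in advance, so this test decides nothing. Mean noise was lowest in scan 6, at 0.157 against 0.235 and 0.166 in scans 1 and 5. Lower noise let the segmentation find more of the simulated steps, which bounded pieces of at least 20 probes. Over the noise range that scans 5 and 6 both hold, tumours of scan 6 had 174 more breakpoints on average, 134 to 409 (n = 13) against 63 to 119 (n = 5), which argues against noise as the whole cause. In scan 6, 56.5% of focal pieces had ends equal to those on another array of the scan, against 12.9% and 8.47% in scans 1 and 5, and 16.25% against 2.88% and 2.76% per pair of arrays, so a shared reference or hybridisation effect may add breakpoints. Copy number variants inherited by these mice would be shared in the same way and were not tested. Focal gains at chromosome 3, 55933618, and chromosome 7, 35316048, were called in 14 tumours of scan 6 and 0 of scans 1 and 5. Although pieces hold at least 5 probes, the stretch with the most calls was 1 probe in each. The level of that probe reached 6.7 on chromosome 3 and 6.9 on chromosome 7. In line 778 the gain on chromosome 7 was called in 778_Tel 2 and 778_ALT 1, 2 and 4, all of scan 3. It was not called in 778_Tel 3 of that scan, nor in the scan 4 samples (parental, 778_Tel 1 and 778_ALT 3). The gain on chromosome 3 was called in 778_ALT 1 only, also of scan 3. Inheritance alone would not give such differences within 1 line, and the other shared pieces were not examined in this way. No biological explanation was tested, since the scan holds 7 G1_OHT, 2 G3_OHT and 5 G3_VEH tumours.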

How the results depend on the processing

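Alternatives by scan and slide, without doubtful arrays or labels (475 and 484, 691 and 691N, 778_ALT 4 and 778_Tel 2), without the 3 most frequent focal losses, on 200-kb windows, on all probes of the newer designs, on replicates 1 to 3 without the block, with normexp on median signals, and every alternative for chromosome levels were chosen after seeing the data. Normexp on mean signals, as fixed in advance, was not run, nor was the alternative without antigen receptor loci. The cause of the changes below was not tested. The altered share of G3_OHT minus G1_OHT (6.71) was above 0 in all 18 alternatives, with p under 0.05 in 9. It was not with normexp (4.87), without adjustment for design (5.82), within the newer (5.33) or older design (10), with scan as a block (5.43), within scans 1, 5 and 6 (10, 4.66 and 1.26) or without 691 and 691N (5.80). At the threshold 0.5 it was 3.27. Breakpoints for this comparison (-34.1) were -159 at 0.5 times the penalty, -66.5 without adjustment for design, -72.9 within the newer design, -21.1 with the deposited values and -22.2 at the threshold 0.2, and turned positive with normexp (8.24), double the penalty (11.5), pieces of at least 20 probes (9.77), within the older design (59.0), with scan as a block (52.7) and within scans 1, 5 and 6 (59.0, 21.2 and 63.4). For G3_VEH minus G3_OHT, breakpoints (103) were -6.06 with normexp, -55.9 with scan as a block or within scan 6, 24.7 with the deposited values, 254 at 0.5 times and 25.6 at double the penalty, 8.83 with pieces of at least 20 probes, and 136 without adjustment for design (exact permutation p = 0.0160), and the altered share (-5.39) was -3.71 at the threshold 0.5 (exact permutation p = 0.0480). For G3_VEH minus G1_OHT, breakpoints (30.0) were -27.6 with the deposited values and -2.65 at 0.5 times the penalty, 7.05 with normexp, 4.90 with pieces of at least 20 probes, 1.62 with probe noise as a covariate, 69.7 without adjustment for design, 4.12 without 2582 and 55.1 without 2668. The altered share (-0.0530) was 1.38 with normexp, 0.219 at the threshold 0.2, 1.06 with probe noise as a covariate, 1.18 without adjustment for design, 0.296 with scan as a block or within scan 6, and -1.02 to 1.08 leaving out each G3_VEH tumour. In line 778 the breakpoint difference (153) was 4.25 with normexp, 436 with the deposited values, 281 at 0.5 times the penalty (exact permutation p = 0.0571), 86.5 at double the penalty, 45.6 with pieces of at least 20 probes, 93.7 without 778_ALT 3, and 149 with the parental sample added (exact permutation p = 0.0286). The altered share (2.60) was 5.75 at double the penalty, 0.642 at the threshold 0.5, 0.611 with the parental sample added, 0.0816 without 778_ALT 4 and 778_Tel 2, 0.823 without 778_ALT 3, -8.27 with normexp, -1.66 at the threshold 0.2, and -0.351 to 6.34 leaving out each sample, with the lowest value without 778_Tel 2. The 47 windows called by limma were 0 with normexp (197 at an unadjusted p under 0.05), centring on the mode (231), within scan 3 (211), without 778_ALT 4 and 778_Tel 2 (86) and on 200-kb windows (955), 31 with scan as a block, and 0 to 123 leaving out each sample (0 without 778_ALT 4, 778_Tel 1, 778_Tel 2 or 778_Tel 3, 18 without 778_ALT 1, 27 without 778_ALT 3 and 123 without 778_ALT 2). No limma model could be fitted within scan 4. The smallest adjusted p of each of its 21 alternatives ranged from 0.00475 to 0.326. With the replicate number as a block the count was 0 (221 at an unadjusted p under 0.05), and 0 for replicates 1, 2 and 3 without the block (167). Samples with the same number deviated together with r of -0.091, 0.279 and -0.082, so the numbers do not pair them. Among primary tumours limma called 57 windows within scan 5 and 3 within scan 6 for G3_OHT against G1_OHT, and 3 within scan 6 for G3_VEH against G3_OHT; in the other 16 and 19 alternatives, and in all 20 for G3_VEH against G1_OHT, all 11 over lines and all 11 of the frequencies, the count was 0. The level of chromosome 15, G3_VEH minus G1_OHT (-0.01), was 0.0330 with normexp, 0.00235 as piece level and 0.00683 without adjustment for design. The level of chromosome 18 in line 778 stayed between 0.32 and 0.56 in 18 alternatives.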

Other observations

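The test of the tumours 691 and 691N was chosen after the result was seen. Parts of chromosomes were gained or lost in many primary tumours apart from whole chromosomes. Chromosome 16 was gained from 92000001 to 97000000 in 18 of 29 tumours and lost from 3000001 to 8000000 in 15. Chromosome 1 was gained from 157000001 to 159000000 in 17 tumours, 4 of them G1_OHT, 11 G3_OHT and 2 G3_VEH. Chromosome 5 was gained from 141000001 to 146000000 in 14 tumours and chromosome 2 from 26000001 to 27000000 in 11.

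All 3 ALT samples outside line 778 had chromosome 1 above 0.2, at 0.30 in 852, 0.29 in 2072P and 0.35 in 2186P, where the telomerase-positive partners were at 0.41 in line 2072 and 0.06 in line 2186. Chromosome 1 was at -0.06 ± 0.02 in 778_ALT (n = 4).

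Other splits of the same samples were counted for the comparisons of primary tumours, for which limma and Fisher's exact test called 0. With a real count of 0, each of the 100 splits reaches it by construction, so the 100 of 100 splits decide nothing about chance. The highest other count was 0 for G3_OHT against G1_OHT, 46 for G3_VEH against G3_OHT, 34 for G3_VEH against G1_OHT, and 1 for the frequencies. For ALT against telomerase-positive samples over lines, 10 splits are too few for a share under 0.05. All 10 reach the real count of 0 by construction, and the highest other was 517. Splits with many windows where the real one has 0 point to a structure of the samples, which was not tested. Windows of 1 chromosome are not independent, so a few tumours with a whole-chromosome change can make such a split.

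The tumours 691, labelled G3, and 691N, labelled G1, shared 75% of focal losses with equal ends (6 of 8), where the highest of 35 pairs of different tumours in scan 1 was 28.6%. A candidate explanation is that both arrays hold DNA of 1 tumour or 1 animal. Whole chromosomes differed, with chromosome 12 at 0.60 in 691 and 0.02 in 691N, chromosome 15 at 0.27 and -0.03 and chromosome 10 at 0.03 and 0.22, which 1 uniform tumour would not give. Their profiles had an r of 0.58 across windows, which are not independent, and the highest of 405 unrelated primary pairs was 0.599.

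The tumours 2713, labelled G3, and 2714, labelled G1, lay on 1 slide and shared 36 focal losses with equal ends, the highest count of 405 unrelated primary pairs. As a share this was 32.7%, and the highest of 91 pairs of scan 6 was 37.5%. The cause was not tested.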
